A study of Mus musculus with 14 samples.

How the data were processed

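The series holds 14 expression arrays of sorted mouse regulatory T cells, the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses. The cells were sorted by CD4 and a green fluorescent protein reporter of Foxp3, from mice of the C57BL/6 background. The title and source labels place 7 arrays in an uninfected (naive) group, 3 in a group infected with Leishmania major and 4 in a group infected with Schistosoma mansoni. L. major is a protozoan given into the skin of the ear, and S. mansoni is a blood fluke that enters through the skin as larvae. Per the labels' protocols, a small amount of total RNA was treated with DNase, amplified as whole-transcript cDNA and labelled with biotin. The labels describe the animals as female and name more than 1 breeding facility, without saying which animals came from which. They give no tissue and no time after infection. Differences of tissue, time or facility between the groups therefore cannot be told apart from an effect of infection. Nothing in the labels says that replicates are separate mice, so the p-values measure only the spread between these samples, which may be technical.

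The deposited table holds log2 expression values of 35557 probe sets, made by the authors with robust multi-array averaging (RMA), per the submitters' processing notes; the version of RMA is not given in the sources used here. All 14 value columns were used and no value was missing. The array medians lay between 7.56 and 7.68 over all probe sets. The number of arrays limits the precision.

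Probe sets were named from the platform annotation. Of the 35557, 21789 had 1 gene symbol, 1621 had several and 12147 had none; the last 2 kinds were left out. Each gene was represented by its probe set with the highest mean over all arrays, which gave 19938 genes, 999 of them with more than 1 probe set. Of the genes, 19855 matched a reference table of mouse genes (assembly GRCm38.p6) through their Entrez identifiers, and 0 symbols needed updating. No genome sequence was used, and no coordinates are given.

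Each comparison was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in a one-way layout over all 14 arrays, with two-sided tests and Benjamini-Hochberg adjustment over the 19938 genes within a comparison. The residual degrees of freedom were 11 and the prior ones 3.99. A gene with an adjusted p under 0.05 is called changed. Fold changes are differences of group means on the log2 scale, given with limma's moderated standard error (SE), and every adjusted p of a gene comes from limma. The test was first run on simulated data for the same 19938 genes in each comparison. With no gene changed it called 0 genes and 0 lists in each comparison. The genes were simulated as independent of each other, so the 0 lists do not show how often lists of correlated genes are called. With 2 sets of genes changed, of the 100 changed by 0.5 (log2), it recovered 79% for L. major against naive, 81% for S. mansoni against naive and 74% for S. mansoni against L. major; of 100 changed by 1, it recovered 97%, 97% and 96%. It also called 43, 9 and 48 genes that had not been changed. In the 2 comparisons with L. major these made up more than 0.05 of all calls. Each group was simulated with its own spread. The adjusted p values of those 2 comparisons may therefore be too low.

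The comparisons, the tests, 36 gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. The lists held 521 members in total, of which 465 were measured (1 through a synonym). Some genes stand in more than 1 list, so the list calls are not separate results. Il2ra, Il2rb, Socs2, Tnfrsf4 and Tnfrsf18 are in both the core regulatory T cell and the IL-2 and STAT5 lists. Itgae and Lrrc32 are in the core and TGF-beta lists, and Ccr8 in the effector, T helper 2 and chemokine receptor lists. The T cell lists were core regulatory T cell, effector regulatory T cell, resting or central T cell, T helper 1, T helper 2, T helper 17, follicular helper, chemokine receptor and adhesion, and T cell receptor signalling genes. The cell state lists were cell cycle, type I interferon stimulated, interferon gamma response, IL-2 and STAT5 response, NF-kappaB response, TGF-beta pathway, apoptosis, glycolysis, oxidative phosphorylation, cholesterol synthesis and unfolded protein response genes. Immediate early, heat shock and ribosomal protein genes stood for handling and RNA quality. Markers of other cells covered B cells, plasma cells, macrophages and monocytes, neutrophils, eosinophils with basophils and mast cells, dendritic cells, cytotoxic T and natural killer cells, erythroid cells, platelets, hepatocytes, keratinocytes, fibroblasts and endothelium. Lists with at least 5 measured members were tested with camera (limma) at its preset correlation of 0.01 between genes, adjusted over the 34 lists tested per comparison; the erythroid list (3 measured) and the platelet list (4 measured) were too small. A list test asks whether the members moved relative to all other genes. Each list test was repeated with a correlation estimated from the data. Where leaving out an array moved a list count that stayed at 2 or fewer, the text gives the move only in part.

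The rule for the genes named in the text takes, per comparison, the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap between the groups. It leaves out predicted symbols, immunoglobulin and T cell receptor segments, olfactory receptors, small RNAs and Y-linked genes, which are counted and not named. It also takes up to 4 called members of each tested list with the smallest adjusted p, of which the text prints a part. Genes always named, whatever their values, included Foxp3, Il10, Ifng, Tbx21, Gata3, Prdm1, Irf4, Il4, Il2, Bcl6, Foxo1, Foxo3, Bach2, Cd2ap, Mir182, Mir10a, Ctla4 and Il2ra. Genes named outside this rule are marked where they are named as chosen after their values were seen.

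Both infections were set against the same naive arrays, so their fold changes share chance values. The covariance of the 2 sets of fold changes was set beside that of 100 simulated pairs of unchanged groups, made by shuffling the arrays' deviations from their group means, rescaled for the size of the group and with the sign of each array drawn at random, and was computed again with the naive arrays split into a set of 3 for one infection and 4 for the other, in each of the 70 ways. Counts of calls in common were set beside the number that independent lists would share.

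The first set of alternatives was a trended prior, a robust prior, array weights, a second quantile normalization, centring of each array on its median, the genes above the median signal, the mean of a gene's probe sets, a fit of only the 2 groups compared, the replicate number as a block, a further threshold of a 2-fold change, and leaving out each array in turn. Weights per group and the standard deviation of each array's values as a covariate were added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.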

Results

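Expression was measured on 14 arrays of regulatory T cells sorted by CD4 and Foxp3: 7 from naive mice, 3 from mice infected with L. major and 4 from mice infected with S. mansoni. The stated design sets infection against the naive state, and the series title names the microRNAs miR-182 and miR-10a. Between arrays of one group, Pearson's r across genes, which are not independent replicates, was 0.975 to 0.992 for naive, 0.972 to 0.983 for S. mansoni and 0.916 to 0.953 for L. major. No pair of arrays held identical values. The median standard deviation (SD) of a gene within its group was 0.102 on the log2 scale for naive, 0.122 for S. mansoni and 0.149 for L. major. L. major replicate 3 scored -52.2 on the first principal component, which held 35.8% of the variance, and the other arrays scored -22.8 to 18.3. The SD of an array's values over all genes was 1.35 to 1.41 on the L. major arrays, 1.41 to 1.48 on the naive arrays and 1.44 to 1.52 on the S. mansoni arrays.

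The first comparison asked what differed in regulatory T cells of L. major infection. Il10, which encodes the inhibitory cytokine IL-10, rose 6.23-fold against naive (log2 2.64 ± 0.20, SE, n = 3 against 7; limma adjusted p = 5.9e-06), and Gzmb, the cytotoxic protease granzyme B, rose 8.40-fold (3.07 ± 0.34). Hspa1a, a stress-inducible Hsp70 chaperone, rose 14.8-fold (3.89 ± 0.47). The chemokine receptor Ccr2 (2.12 ± 0.33) and the inhibitory receptor Havcr2, also called TIM-3 (2.06 ± 0.29), rose as well. Itga4, the integrin subunit alpha 4 used in homing to tissue, fell by 1.59 ± 0.13 (adjusted p = 9.5e-06).

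The remaining large rises were in Gem (2.76 ± 0.28), the aspartate aminotransferase Got1 (2.25 ± 0.19), Dennd4a (2.14 ± 0.23), the triglyceride synthesis enzyme Dgat1 (2.14 ± 0.16) and Vps37b (2.06 ± 0.15). Large falls were measured for Sp140 (-2.07 ± 0.56), the activating receptor Cd226 (-1.61 ± 0.19), the NADPH oxidase subunit Cybb (-1.59 ± 0.20), the peptidase Dpp4 (-1.53 ± 0.18), Nifk (-1.49 ± 0.21) and Cyria (-1.67 ± 0.33). The zinc finger genes Zfp626 (-1.91 ± 0.28), Zfp518a (-1.59 ± 0.27) and Zfp729b (-1.45 ± 0.31) fell too. The Sp140 call was lost with only the 2 groups in the fit (-2.07, adjusted p = 0.0515). With the SD of each array as a covariate, an alternative added after seeing the data, the calls of Sp140 (-0.99, adjusted p = 0.550), Cyria (-0.89, 0.216), Zfp729b (-0.70, 0.287), Zfp518a (-0.86, 0.0653) and Zfp626 (-1.45, 0.0564) were lost. Sp140 was at 4.81 on L. major replicate 3, at 8.49 and 8.72 on replicates 1 and 2, and at 9.21 to 9.53 on the naive arrays.

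Effector regulatory T cell genes rose as a group: 12 of 21 measured members rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 1.6e-06; adjusted p = 0.405 with an estimated correlation). Besides Il10, Gzmb and Havcr2, they included the chemokine receptor Ccr8 (1.85 ± 0.24), the co-stimulatory receptor Icos (1.11 ± 0.13), and the transcription factors Prdm1 (1.36 ± 0.26) and Irf4 (0.66 ± 0.12). The effector list mean stood 1.20, 0.33 and 0.96 above naive on L. major replicates 1, 2 and 3, and 6 of the 21 genes were highest on replicate 1, the array with keratinocyte markers. Without that array 9 effector genes rose. Of 19 core regulatory T cell genes, 9 rose and 1 fell, or 11 and 2 adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.405 with an estimated correlation). Itgae, the CD103 integrin chain (1.31 ± 0.13), the receptor Tnfrsf4, or OX40 (0.65 ± 0.088), and the inhibitory receptor Ctla4 (0.46 ± 0.074) rose. Foxp3 itself differed by 0.32 ± 0.11 (adjusted p = 0.0685) and Il2ra, the IL-2 receptor alpha chain, by 0.17 ± 0.068 (adjusted p = 0.0916), neither past the threshold.

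Glycolysis genes rose in 12 of 14 cases and fell in 0, with the same counts adjusted over the list alone (adjusted p = 1.3e-04; adjusted p = 0.405 with an estimated correlation). The glucose transporter Slc2a1 (1.11 ± 0.13), the lactate transporter Slc16a3 (0.74 ± 0.13), Ldha (0.65 ± 0.12) and Hk2 (0.76 ± 0.16) were among them. The mean of this list stood 0.93, 0.15 and 0.68 above the naive mean on L. major replicates 1, 2 and 3, and 10 of its 14 genes were highest on replicate 1. That array also carried the markers of keratinocytes, with a list mean 1.84 above naive against 0.014 and 0.14 on replicates 2 and 3. Without L. major replicate 3, 7 glycolysis genes rose. Oxidative phosphorylation genes went the other way: 0 of 25 rose and 7 fell, with the same counts adjusted over the list alone (adjusted p = 1.3e-04; adjusted p = 0.406 with an estimated correlation), Sdha among them (-0.60 ± 0.11). That count was 1 without L. major replicate 3 and 4 without naive replicate 1, 6 or 7. With the SD of each array as a covariate the oxidative phosphorylation call was lost (adjusted p = 0.713), as were those of Sdha (-0.37, 0.161), Slc16a3 (0.61, 0.121), Ldha (0.66, 0.0807) and Hk2 (0.54, 0.218).

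Heat shock genes rose in 6 of 8 cases, or 7 adjusted over the list alone, and none fell (adjusted p = 0.0011; adjusted p = 0.406 with an estimated correlation). The list mean was 1.41, 1.20 and 0.86 above naive on L. major replicates 1, 2 and 3, and between -0.33 and 0.32 on the naive arrays. Without L. major replicate 1, 4 heat shock genes rose. The chaperone Hsph1 rose by 1.88 ± 0.44, a call lost with array weights (1.90, adjusted p = 0.108), weights per group (1.88, 0.127) and the SD covariate (2.06, 0.133) although the change was no smaller, and 7 of the 8 heat shock genes were highest on L. major replicate 1, the array with the keratinocyte markers. Immediate early genes, which respond within minutes to stimulation or handling, rose in 11 of 18 cases and fell in 1, or 14 and 1 adjusted over the list alone (adjusted p = 2.2e-04; adjusted p = 0.485 with an estimated correlation). Nr4a1 (0.92 ± 0.15) and Nr4a2 (1.33 ± 0.22) rose while Egr2 fell by 0.59 ± 0.13, with the calls of Nr4a1 (0.63, 0.0904) and Nr4a2 (0.89, 0.0931) lost with the SD covariate. Leaving out L. major replicate 3 left 6 that rose. Of 13 NF-kappaB response genes 3 rose, or 5 adjusted over the list alone, and 0 fell (camera adjusted p = 0.0344, or 0.560 with an estimated correlation), Rel (0.76 ± 0.11) among them. The NF-kappaB call was lost without L. major replicate 1 (adjusted p = 0.353) or naive replicate 6 (0.0508), and 6 genes rose without L. major replicate 2.

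T cell receptor signalling genes fell on balance: 2 of 16 rose and 7 fell, or 2 and 8 adjusted over the list alone (camera adjusted p = 7.7e-04, or 0.405 with an estimated correlation). Their list mean, minus naive, was -0.30, -0.060 and -0.26 on L. major replicates 1, 2 and 3. On the naive arrays it was -0.085 to 0.066, a range that held replicate 2. Prkcq, a kinase downstream of the receptor, fell by 1.09 ± 0.19 and the CD3 chain Cd3d by 0.69 ± 0.13; the call was lost among the genes above the median signal (adjusted p = 0.0548) and with the SD of each array as a covariate (0.0700), which also ended those of Prkcq (-0.91, 0.109) and Cd3d (-0.39, 0.154). Of 21 type I interferon stimulated genes, 0 rose and 4 fell, or 0 and 7 adjusted over the list alone (adjusted p = 1.3e-04; adjusted p = 0.405 with an estimated correlation). The RNA sensor Ifih1 (-0.96 ± 0.15) and Usp18 (-0.73 ± 0.15) were among the 4. The SD covariate ended the interferon list call (adjusted p = 0.629) and the calls of Ifih1 (-0.79, 0.0621) and Usp18 (-0.30, 0.215), and weights per group that of Usp18 (-0.73, 0.0521). Ribosomal protein genes numbered 0 risen and 6 fallen of 21, with the same counts adjusted over the list alone (adjusted p = 1.3e-04; adjusted p = 0.485 with an estimated correlation), such as Rpl30 (-0.64 ± 0.15). This 6 became 1 without L. major replicate 3, 2 without L. major replicate 1 and 3 without naive replicate 1, 3, 6 or 7, and the SD covariate ended the list call (0.346) and that of Rpl30 (-0.30, 0.378).

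The other 24 lists tested were not called (lowest adjusted p = 0.115), although single members changed, and 0 of the 10 list calls held with an estimated correlation. The chemokine receptor, interferon gamma, macrophage and neutrophil lists had a positive median change and a downward test. Of the chemokine receptor and adhesion genes 7 of 22 rose and 5 fell, or 7 and 7 adjusted over the list alone (adjusted p = 0.566), and 3 fell without naive replicate 1, 3, 5, 6 or 7. Cxcr5, the receptor that guides T cells to B cell follicles, fell by 1.36 ± 0.17, while Bcl6, the factor that directs follicular helper T cells, rose by 0.68 ± 0.11. The follicular helper list held 3 risen and 1 fallen of 10, the same counts adjusted over the list alone (adjusted p = 0.734). Of 10 TGF-beta pathway genes 6 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.115); 3 rose without L. major replicate 1 or naive replicate 1 and 2 without L. major replicate 3. Among T helper 17 genes 3 of 8 rose and 0 fell, or 5 and 1 adjusted over the list alone (adjusted p = 0.115), including the factor Rora (1.05 ± 0.13); 5 rose without L. major replicate 2. Cell cycle genes counted 4 risen of 32, the same adjusted over the list alone (adjusted p = 0.115), and 0 without L. major replicate 3. T helper 1 genes counted 1 risen and 1 fallen of 13, or 4 and 1 adjusted over the list alone (adjusted p = 0.507), with 5 risen without L. major replicate 2. The fallen one was the chemokine receptor Cxcr3 (-0.80 ± 0.25, adjusted p = 0.0409), a call lost without L. major replicate 3 (0.228) and without naive replicate 1, 3, 5, 6 or 7 (0.0532 to 0.0691). Ccr7, the lymph node homing receptor, rose by 0.61 ± 0.19 (adjusted p = 0.0453), lost without L. major replicate 2 (0.117) or 3 (0.0712) and without any 1 naive array (0.0579 to 0.0727).

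Further lists not called for L. major were T helper 2 genes (2 of 13 rose, 3 and 1 fallen adjusted over the list alone; adjusted p = 0.492), IL-2 and STAT5 response genes (4 of 10 rose in both countings; 0.115) and unfolded protein response genes (4 of 16, or 5 adjusted over the list alone; 0.115). The IL-2 and STAT5 count was 2 without L. major replicate 1 or 3, and the unfolded protein count was 0, 2 and 7 without L. major replicates 3, 1 and 2. Resting or central T cell genes counted 1 risen and 0 fallen of 14, or 2 and 1 adjusted over the list alone (adjusted p = 0.115), with 6 fallen without L. major replicate 2. Interferon gamma response genes counted 1 risen and 1 fallen of 15, or 3 and 2 adjusted over the list alone (0.734), with 3 risen without L. major replicate 2. Apoptosis genes counted 2 risen and 1 fallen of 10, or 4 and 2 adjusted over the list alone (0.909), and cholesterol synthesis genes 0 and 0 of 16 (0.278). Of the lists for other cells, 0 members rose or fell among B cell (adjusted p = 0.827), macrophage (0.734), neutrophil (0.588), eosinophil, basophil and mast cell (0.909) and dendritic cell genes (0.501). In the plasma cell (0.477), cytotoxic T and natural killer cell (0.492) and hepatocyte (0.285) lists 1 member each rose, or 1, 0 and 0 adjusted over the list alone, and without L. major replicate 2, 3 rose in each of the last 2. Of 6 fibroblast genes 2 rose, or 3 adjusted over the list alone (0.115), and of 6 endothelial genes 2 rose, or 3 adjusted over the list alone (0.394). The fibroblast count was 1 without L. major replicate 1 or naive replicate 4 and 0 without naive replicate 1, 3, 5, 6 or 7. The endothelial count was 0 without L. major replicate 1 or 3 and 1 without naive replicate 1, 2, 3, 5 or 6. The hepatocyte count was 0 without L. major replicate 1 or 3 or naive replicate 1, 3, 4, 5, 6 or 7, the plasma cell count 0 without L. major replicate 1 and 2 without L. major replicate 2, and the cytotoxic count 0 without L. major replicate 3 or naive replicate 1, 3, 4 or 5. Keratinocyte genes passed the threshold in 0 of 7 cases, or 6 adjusted over the list alone (adjusted p = 0.115), and in 5 without L. major replicate 2. Of the erythroid and platelet lists, too small to test, Pf4, named after its values were seen, rose by 0.33 (adjusted p = 0.0368).

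Of the genes named in advance, Tbx21, the T helper 1 factor, differed by 0.11 ± 0.11 (adjusted p = 0.465), Gata3, the T helper 2 factor, by 0.16 ± 0.077 (0.139), Ifng by 0.31 ± 0.30 (0.432), Il4 by -0.022 ± 0.10 (0.884) and Il2 by 0.14 ± 0.073 (0.164). Foxo1 (-0.22 ± 0.074, 0.0565), Foxo3 (-0.0041 ± 0.064, 0.965), Bach2 (-0.39 ± 0.16, 0.0877) and Cd2ap (-0.38 ± 0.15, 0.0871) were not called either. The probe set for Mir182 differed by 0.078 ± 0.074 (0.435). That for Mir10a differed by 1.27 ± 0.56 (0.115) and was at 7.14 on L. major replicate 2 and 3.20 to 3.54 on the other 13 arrays. Mir182 was at 5.39 to 5.78, and both probe sets lay below the array medians of 7.56 to 7.68. In none of the comparisons do these values show whether the microRNAs miR-182 and miR-10a themselves changed.

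In all, limma called 3261 of 19938 genes for L. major, 1706 higher and 1555 lower, with a median absolute log2 change of 0.39; 188 changed at least 2-fold, 88 up and 100 down. The share higher was 52.3%, and with each array centred on its median it was 39.1% (1057 higher and 1647 lower). The count was 1317 without L. major replicate 3, with 1104 of the 3261 among them, 5121 without L. major replicate 2 and 2052 without naive replicate 3. Without L. major replicate 1, the array with keratinocyte markers, it was 2999, with 2092 of the 3261 among them. With the SD of each array as a covariate, added after seeing the data, 247 genes were called, 234 of them among the 3261, and 11 lists were called upward and 0 downward, where 6 and 4 had been. It also ended the calls of Prdm1 (1.15, adjusted p = 0.145), Irf4 (0.63, 0.0734), Bcl6 (0.58, 0.0824), Ccr7 (0.72, 0.225) and Cxcr3 (-0.34, 0.665), where the change of Ccr7 was larger than without the covariate and that of Irf4 near it.

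**Figure D1:**
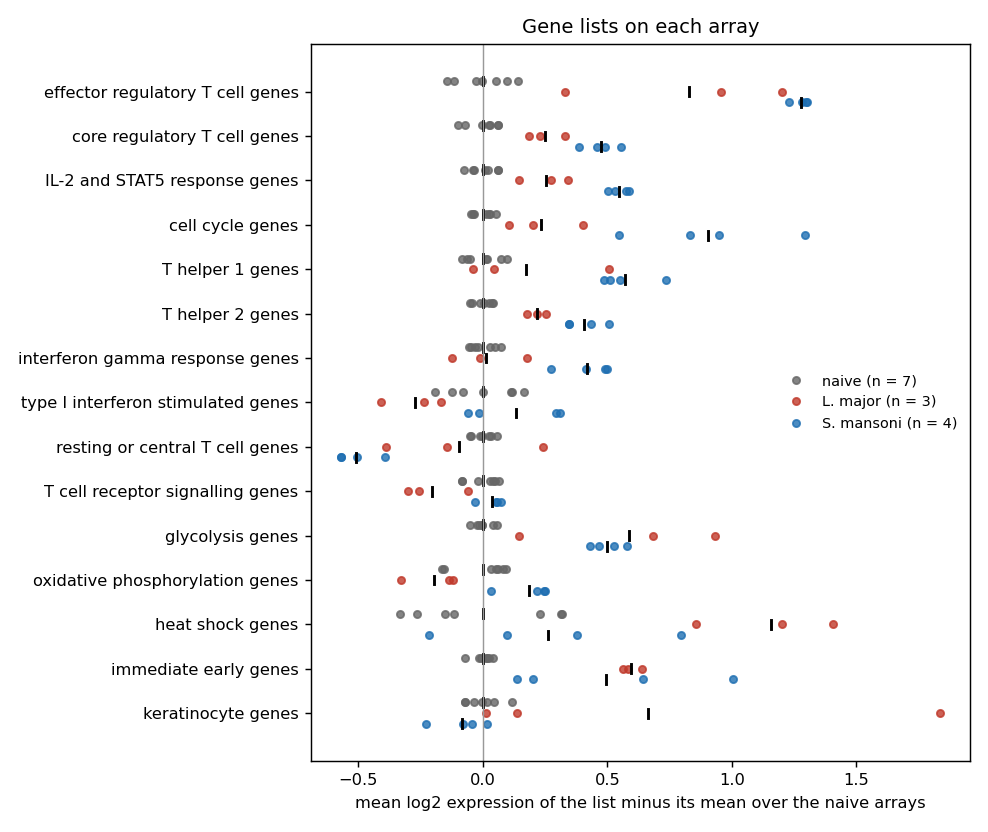
Mean log2 expression of 15 gene lists on each array, minus the list's mean over the naive arrays (x axis, log2 units), for naive (n = 7), L. major (n = 3) and S. mansoni (n = 4); points are arrays and black ticks are group means. The keratinocyte mean of 1 L. major array lies at 1.84, and the cell cycle means of the 4 S. mansoni arrays lie between 0.55 and 1.29.

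The second comparison asked the same of S. mansoni infection. Gzmb rose 14.5-fold against naive (log2 3.86 ± 0.31, SE, n = 4 against 7; limma adjusted p = 3.1e-06) and Il10 rose 8.15-fold (3.03 ± 0.18, adjusted p = 2.8e-07). Fgl2, a secreted mediator of suppression by regulatory T cells, rose 6.14-fold (2.62 ± 0.17). Mki67, a marker of dividing cells, rose by 1.93 ± 0.16 and Tbx21 by 1.20 ± 0.10 (adjusted p = 4.2e-06). Cxcr5 fell by 1.32 ± 0.15 and Bach2, a repressor of effector differentiation, by 0.75 ± 0.14 (adjusted p = 0.0045).

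Other large rises were in the immunoglobulin-like receptors Lilr4b (3.55 ± 0.33) and Lilrb4a (3.09 ± 0.35), Ccr2 (2.42 ± 0.30), the mitotic kinesin Kif11 (2.32 ± 0.20), the cytotoxic granule protein Nkg7 (2.30 ± 0.17), the centromere protein Cenpk (2.26 ± 0.25) and the inhibitory receptor Klrg1 (2.21 ± 0.23). Large falls were found for Parp8 (-1.79 ± 0.24), Tespa1 (-1.53 ± 0.20), Dzip1 (-1.33 ± 0.15), Arhgap5 (-1.31 ± 0.20), the co-stimulatory ligand Cd86 (-1.29 ± 0.17), the inhibitory receptor Btla (-1.28 ± 0.21) and the actin cross-linker Actn1 (-1.20 ± 0.20). Ift80 fell by 1.23 ± 0.26, a call lost without S. mansoni replicate 3 (adjusted p = 0.0516). Cd96 fell by 1.19 ± 0.28, lost without S. mansoni replicate 2 (0.0801) or 3 (0.0821).

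Cell cycle genes rose in 24 of 32 cases and fell in 0, or 30 and 0 adjusted over the list alone (camera adjusted p = 1.4e-45; adjusted p = 0.0064 with an estimated correlation). The replication helicase subunit Mcm3 rose by 0.68 ± 0.067 and the topoisomerase Top2a by 2.19 ± 0.21, although a second, dimmer probe set of Top2a differed by only 0.070. Effector regulatory T cell genes rose in 15 of 21 cases and fell in 0, or 18 and 0 adjusted over the list alone (adjusted p = 8.2e-34; adjusted p = 0.0062 with an estimated correlation), with Lag3 (1.61 ± 0.13) and Prdm1 (1.94 ± 0.24) among them. Core regulatory T cell genes rose in 11 of 19 cases and fell in 0, or 13 and 2 adjusted over the list alone (adjusted p = 7.2e-16; adjusted p = 0.0028 with an estimated correlation), including Itgae (1.86 ± 0.12), Tnfrsf4 (0.94 ± 0.080) and Socs2 (1.10 ± 0.12, or 0.56 by a second probe set). Foxp3 differed by 0.15 ± 0.10 (adjusted p = 0.542). Ctla4 rose by 0.27 ± 0.067 (adjusted p = 0.0269), a call lost without naive replicate 1 (0.0514), 2 (0.0516), 3 (0.0530) or 4 (0.0541) and S. mansoni replicate 2 (0.0620), 3 (0.118) or 4 (0.0779), and under a second quantile normalization (0.0804). Resting or central T cell genes moved down: 10 of 14 fell and 0 rose, or 11 and 0 adjusted over the list alone (adjusted p = 3.4e-11; adjusted p = 0.0237 with an estimated correlation). Besides Bach2, these included the transcription factors Foxp1 (-0.88 ± 0.14) and Foxo1 (-0.37 ± 0.067), and the IL-6 receptor Il6ra (-0.55 ± 0.080).

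Genes of both T helper 1 and T helper 2 cells rose. Of 13 T helper 1 genes 6 rose and 0 fell, or 8 and 1 adjusted over the list alone (adjusted p = 7.5e-09; adjusted p = 0.0185 with an estimated correlation), the chemokine Ccl5 (1.73 ± 0.19) and Cxcr3 (1.03 ± 0.23) with Tbx21; 3 rose without S. mansoni replicate 3. Of 13 T helper 2 genes 6 rose and 0 fell, the same adjusted over the list alone (adjusted p = 5.1e-08; adjusted p = 0.0034 with an estimated correlation), among them Ccr8 (2.20 ± 0.21), the nuclear receptor Pparg (0.95 ± 0.075) and Gata3 (0.57 ± 0.070). Il4 rose by 0.34 ± 0.094 (adjusted p = 0.0487), a call lost without any 1 naive array (0.0513 to 0.0932) and without S. mansoni replicate 2 (0.150), 3 (0.167) or 4 (0.0638). Interferon gamma response genes rose in 9 of 15 cases and fell in 0, or 10 and 0 adjusted over the list alone (adjusted p = 3.4e-11; adjusted p = 0.0034 with an estimated correlation), including the GTPases Iigp1 (1.00 ± 0.14) and Gbp3 (0.77 ± 0.12) and the factor Irf1 (0.53 ± 0.085, or 0.42 by a second probe set). Ifng itself differed by 0.89 ± 0.27 (adjusted p = 0.0757). Chemokine receptor and adhesion genes rose in 9 of 22 cases and fell in 4, or 9 and 5 adjusted over the list alone (adjusted p = 2.6e-04; adjusted p = 0.0273 with an estimated correlation), and 2 fell without S. mansoni replicate 3.

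IL-2 and STAT5 response genes rose in 7 of 10 cases and fell in 0, or 9 and 0 adjusted over the list alone (adjusted p = 1.9e-14; adjusted p = 2.9e-04 with an estimated correlation), with Il2ra up by 0.45 ± 0.062. TGF-beta pathway genes rose in 4 of 10 cases, or 6 adjusted over the list alone, and none fell (adjusted p = 2.0e-07; adjusted p = 0.0034 with an estimated correlation), the receptor Tgfbr1 (0.71 ± 0.13) and the integrin chain Itgb8 (0.95 ± 0.16) among them. Glycolysis genes rose in 9 of 14 cases and fell in 0, the same adjusted over the list alone (adjusted p = 3.4e-11; adjusted p = 0.0460 with an estimated correlation), such as Tpi1 (1.36 ± 0.25) and Ldha (0.63 ± 0.11). Of the markers of other cells, the cytotoxic T and natural killer list held 3 risen and 0 fallen of 13, or 5 and 1 adjusted over the list alone (adjusted p = 3.5e-05; adjusted p = 0.0102 with an estimated correlation). The 3 were Nkg7, the granule protease Gzma (8.42 against 6.42 on average, adjusted p = 2.8e-07) and Ctsw (1.23 ± 0.14). These 12 list calls held with an estimated correlation, and the following 8 did not.

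Immediate early genes rose in 7 of 18 cases and fell in 0, or 10 and 0 adjusted over the list alone (adjusted p = 3.4e-11; adjusted p = 0.0842 with an estimated correlation), Nr4a1 (0.86 ± 0.14) and Egr2 (0.64 ± 0.12) among them. The immediate early list mean, minus naive, was 1.00 and 0.64 on S. mansoni replicates 2 and 3 and 0.20 and 0.14 on replicates 1 and 4, and the heat shock list mean was also highest on replicate 2, at 0.79. Oxidative phosphorylation genes rose in 4 of 25 cases, or 6 adjusted over the list alone, and none fell (adjusted p = 9.4e-07; adjusted p = 0.157 with an estimated correlation), Sdhb included (0.42 ± 0.063), and 2 rose without S. mansoni replicate 1, 3 or 4; the SD covariate ended this list call (0.266). Unfolded protein response genes rose in 3 of 16 cases, or 7 adjusted over the list alone, and none fell (adjusted p = 1.0e-05; adjusted p = 0.105 with an estimated correlation), with Manf at 0.41 ± 0.059; 1 rose without S. mansoni replicate 4. Of 21 type I interferon stimulated genes 1 rose and 1 fell, or 3 and 1 adjusted over the list alone, with the list test upward (adjusted p = 0.0052; adjusted p = 0.362 with an estimated correlation). That call was lost without S. mansoni replicate 1 (0.0547) or 4 (0.144), with the SD covariate (0.990, test downward) and among the genes above the median signal (0.150). Of 13 NF-kappaB genes 1 rose, the same adjusted over the list alone (adjusted p = 0.0115; adjusted p = 0.330 with an estimated correlation), lost without S. mansoni replicate 2 (0.130), under a second quantile normalization (0.140) and among the genes above the median signal (0.0746). Follicular helper genes counted 1 risen and 3 fallen of 10, or 2 and 4 adjusted over the list alone (adjusted p = 0.0267; adjusted p = 0.189 with an estimated correlation), lost without S. mansoni replicate 2 (0.0672) and among the genes above the median signal (0.0540). Cd200 fell by 0.75 ± 0.14, and Bcl6 fell by 0.40 ± 0.10 (adjusted p = 0.0357), a call lost without S. mansoni replicate 1 (0.139) or 3 (0.0863) and naive replicate 1, 2, 3, 4, 6 or 7 (0.0510 to 0.0634).

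Ribosomal protein genes (test downward, adjusted p = 0.0207; adjusted p = 0.545 with an estimated correlation) and hepatocyte genes (test upward, adjusted p = 0.0181; adjusted p = 0.189 with an estimated correlation) had list calls with 0 members called in either counting. The ribosomal call was lost without S. mansoni replicate 2 (0.460) or naive replicate 3 (0.0639) or 6 (0.0646), and the hepatocyte call without S. mansoni replicate 4 (0.182) and with the SD covariate (0.109). Alb, the hepatocyte secretory protein albumin, named here after its values were seen, was at 8.43, 7.31, 7.27 and 9.06 on S. mansoni replicates 1 to 4 and at 6.80 to 7.45 on the naive arrays. The remaining 14 lists were not called (lowest adjusted p = 0.0596, T cell receptor signalling, 2 of 16 risen). T helper 17 genes counted 1 fallen of 8 (0.409), the chemokine receptor Ccr6 (-1.08 ± 0.14), and apoptosis genes 3 risen of 10 (0.138), with 1 without naive replicate 3 or S. mansoni replicate 3 and 0 without S. mansoni replicate 2. Heat shock genes counted 0 (0.106), although the list mean on S. mansoni replicate 2 was 0.79 and on the others -0.22 to 0.38. Keratinocyte genes counted 0 (adjusted p = 0.605).

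Cd2ap fell by 0.84 ± 0.14 (adjusted p = 0.0014). Irf4 (0.32 ± 0.10, adjusted p = 0.112), Il2 (-0.11 ± 0.066, 0.470), Foxo3 (-0.0076 ± 0.059, 0.968), Mir182 (-0.0069 ± 0.067, 0.975) and Mir10a (0.019 ± 0.51, 0.993) were not called. For S. mansoni limma called 1041 genes, 698 higher and 343 lower, with a median absolute log2 change of 0.52, and 146 changed at least 2-fold, 124 up and 22 down. The count was 692 without S. mansoni replicate 3, with 662 of the 1041 among them, 511 higher and 181 lower in all. The split was 792 higher and 245 lower with each array centred on its median, 638 and 429 under a second quantile normalization, and 644 and 566 with the SD of each array as a covariate, added after seeing the data, which ended the calls of Cxcr3 (0.77, adjusted p = 0.0607), Bcl6 (-0.34, 0.126) and Ctla4 (0.27, 0.0501). With only the 2 groups in the fit it was 1891 and with array weights 1575.

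**Figure D2:**
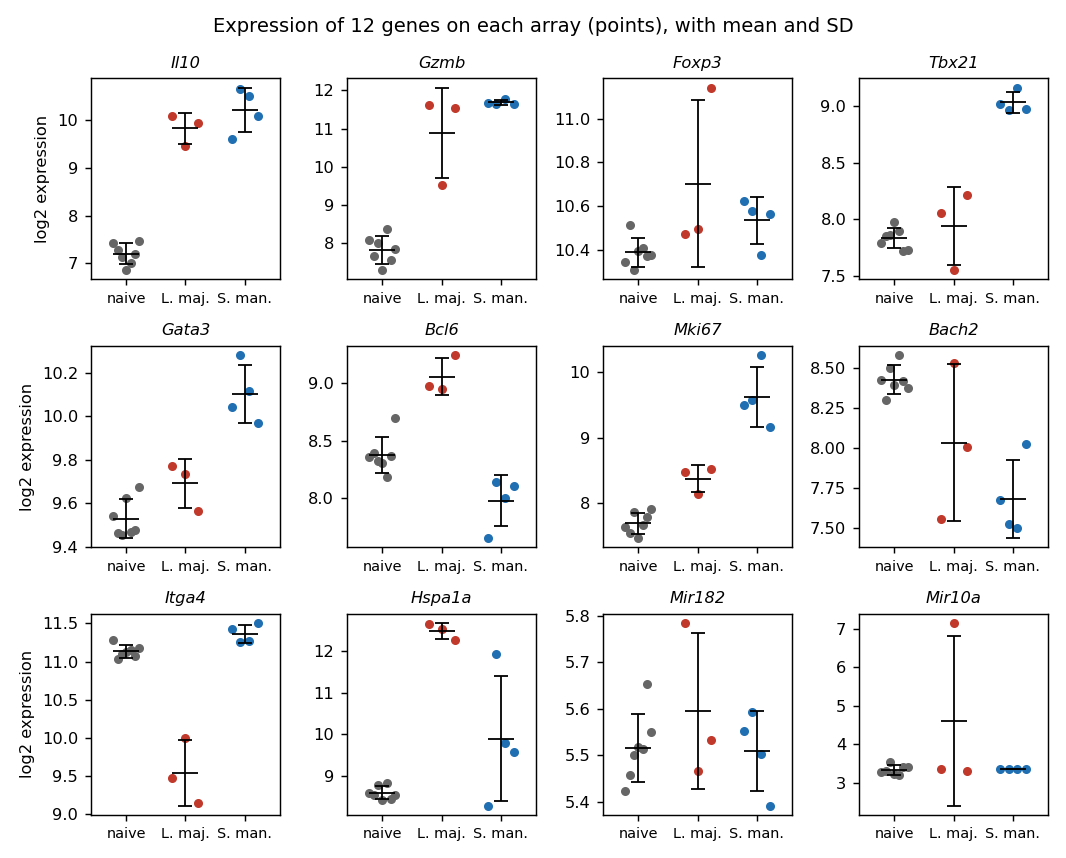
Log2 expression (y axis) of 12 genes on each array by group, naive (n = 7), L. major (n = 3) and S. mansoni (n = 4); points are arrays, with the group mean and SD. Il10 and Gzmb are higher on the arrays of both infections than on the naive arrays, and Mir10a stands at 7.14 on 1 L. major array.

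The direct comparison asked whether the infections differed from each other, with S. mansoni set against L. major. Fgl2 was 4.44-fold higher in S. mansoni (log2 2.15 ± 0.21, SE, n = 4 against 3; limma adjusted p = 4.4e-05), Nkg7 4.70-fold higher (2.23 ± 0.21) and Tbx21 2.13-fold higher (1.09 ± 0.12, adjusted p = 1.6e-04). Mki67 was higher by 1.25 ± 0.19 and Itga4 by 1.82 ± 0.14. Bcl6 was lower by -1.08 ± 0.13, Ccr7 by -1.39 ± 0.21 and Hspa1a by -2.58 ± 0.53. Il10 differed by 0.39 ± 0.22 (adjusted p = 0.177) and Foxp3 by -0.17 ± 0.13 (adjusted p = 0.301).

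Other genes far higher in S. mansoni were Plac8 (2.55 ± 0.23), Tmem273 (2.44 ± 0.17), Lilrb4a (2.40 ± 0.42), Prelid2 (2.26 ± 0.26), Lilr4b (2.26 ± 0.40), the centromere protein Cenph (2.24 ± 0.29) and Klrg1 (2.18 ± 0.29). Sp140 was higher by 2.03 ± 0.62 (adjusted p = 0.0355), a call lost without S. mansoni replicate 1 (0.0792), 3 (0.0521) or 4 (0.0844); it was at 4.81 on L. major replicate 3. Among the genes far lower were Vps37b (-2.14 ± 0.17), Got1 (-1.53 ± 0.20), Dennd4a (-1.53 ± 0.25), Gem (-1.42 ± 0.31), Gramd3 (-1.42 ± 0.11), the G protein regulator Rgs2 (-1.39 ± 0.29) and the co-chaperone Dnajb4 (-1.38 ± 0.25). Hsph1 was lower by -1.66 ± 0.49 (adjusted p = 0.0310), lost without L. major replicate 1 (0.0687) or 3 (0.0533) or S. mansoni replicate 1 (0.0840) or 4 (0.0758).

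Cell cycle genes were higher in 21 of 32 cases and lower in 0, or 22 and 0 adjusted over the list alone (camera adjusted p = 1.3e-18; adjusted p = 0.125 with an estimated correlation), with the kinesin Cenpe at 1.35 ± 0.20. Oxidative phosphorylation genes were higher in 13 of 25 cases, or 17 adjusted over the list alone, and lower in 0 (adjusted p = 2.8e-10; adjusted p = 0.125 with an estimated correlation), including Cox7a2 (0.99 ± 0.22) and Cox5a (0.70 ± 0.14); 6 were higher without L. major replicate 3. For type I interferon stimulated genes the counts were 9 higher and 0 lower of 21, or 10 and 0 adjusted over the list alone (adjusted p = 2.8e-07; adjusted p = 0.125 with an estimated correlation), and 4 without L. major replicate 3 or S. mansoni replicate 1 or 4. Ifih1 was higher by 0.91 ± 0.16 and Ifit1 by 0.95 ± 0.23, the latter lost without L. major replicate 3 (0.0513). Interferon gamma response genes counted 7 higher and 0 lower of 15, or 9 and 1 adjusted over the list alone (adjusted p = 3.6e-05; adjusted p = 0.111 with an estimated correlation), among them Irgm1 (1.67 ± 0.29) and Iigp1 (1.27 ± 0.16). T cell receptor signalling genes counted 7 higher and 1 lower of 16, or 8 and 1 adjusted over the list alone (adjusted p = 6.8e-05; adjusted p = 0.125 with an estimated correlation), Cd3d at 0.93 ± 0.14; a second quantile normalization ended this call (0.0507).

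Effector regulatory T cell genes counted 5 higher and 1 lower of 21, or 6 and 2 adjusted over the list alone (adjusted p = 1.2e-04; adjusted p = 0.350 with an estimated correlation). Lag3 was 2.82-fold higher (SE 0.15, log2) and Icos lower by -0.52 ± 0.14, the Icos call lost without L. major replicate 1 (0.0742) or 3 (0.0878) or S. mansoni replicate 1 (0.0585). The effector count of 5 was 9 without L. major replicate 1 and 3 without L. major replicate 3, and 3 were lower without L. major replicate 2. Core regulatory T cell genes counted 6 higher and 0 lower of 19, the same adjusted over the list alone (adjusted p = 5.8e-04; adjusted p = 0.125 with an estimated correlation), and 3 without L. major replicate 3 or S. mansoni replicate 4, with 3 lower without L. major replicate 2; the call was lost under a second quantile normalization (0.121) and among the genes above the median signal (0.0870). The ectonucleotidase Entpd1, or CD39 (1.16 ± 0.15), and Socs2 (1.00 ± 0.14, or 0.63 by a second probe set) were among the 6. IL-2 and STAT5 response genes counted 4 higher and 0 lower of 10, the same adjusted over the list alone (adjusted p = 1.4e-04; adjusted p = 0.0606 with an estimated correlation), and 2 without L. major replicate 3 or S. mansoni replicate 4. Il2ra was higher by 0.28 ± 0.075 (adjusted p = 0.0222), lost without L. major replicate 3 (0.0869) or S. mansoni replicate 4 (0.0620). Resting or central T cell genes counted 0 higher and 6 lower of 14, or 0 and 7 adjusted over the list alone (adjusted p = 0.0055; adjusted p = 0.350 with an estimated correlation), Foxp1 at -0.77 ± 0.17; the call was lost without L. major replicate 2 (0.118) and 10 were lower without L. major replicate 1.

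T helper 1 genes counted 5 higher and 1 lower of 13, the same adjusted over the list alone (adjusted p = 0.0055; adjusted p = 0.237 with an estimated correlation), with Ccl5 at 1.66 ± 0.23 and Cxcr3 at 1.84 ± 0.27. T helper 2 genes counted 4 higher and 0 lower of 13, or 5 and 1 adjusted over the list alone (adjusted p = 0.0031; adjusted p = 0.125 with an estimated correlation), and 2 without L. major replicate 3, with Pparg at 0.86 ± 0.091 and Gata3 at 0.41 ± 0.085 (adjusted p = 0.0077). Both list calls were lost among the genes above the median signal (0.0895 for T helper 1 and 0.0634 for T helper 2). Il4 was higher by 0.36 ± 0.11 (adjusted p = 0.0388), lost without L. major replicate 1 (0.0534) or 3 (0.153) or S. mansoni replicate 2 (0.0643), 3 (0.0715) or 4 (0.0620). T helper 17 genes counted 0 higher and 5 lower of 8, or 0 and 7 adjusted over the list alone (adjusted p = 0.0187; adjusted p = 0.125 with an estimated correlation), the receptor Il23r (-1.25 ± 0.26) and Rora (-0.81 ± 0.15) among them, and 3 without L. major replicate 1 or 3. Chemokine receptor and adhesion genes counted 7 higher and 4 lower of 22, or 10 and 4 adjusted over the list alone (adjusted p = 0.0030; adjusted p = 0.125 with an estimated correlation), Cxcr4 at -0.85 ± 0.13; 4 were higher without S. mansoni replicate 4, and the call was lost among the genes above the median signal (0.398). TGF-beta pathway genes counted 3 higher and 1 lower of 10, the same adjusted over the list alone (adjusted p = 0.0475; adjusted p = 0.144 with an estimated correlation), Tgfbr1 at 0.75 ± 0.16; 1 was higher without L. major replicate 3 or S. mansoni replicate 4, and the call was lost without L. major replicate 2 (0.101) or S. mansoni replicate 2 (0.119).

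Cytotoxic T and natural killer genes counted 3 higher and 0 lower of 13, the same adjusted over the list alone (adjusted p = 0.0475; adjusted p = 0.160 with an estimated correlation), with Gzma at 1.92 ± 0.15. The test and the mean (0.31) were upward and the median was -0.12, and the call was lost without L. major replicate 2 (0.126, with 3 lower) or S. mansoni replicate 2 (0.0605). Heat shock genes counted 0 higher and 5 lower of 8, the same adjusted over the list alone (adjusted p = 0.0303; adjusted p = 0.486 with an estimated correlation); 2 were lower without L. major replicate 1 or 3 or S. mansoni replicate 1 or 4, and the call was lost without L. major replicate 1 (0.109) or 2 (0.101). No list call of this comparison held with an estimated correlation (lowest adjusted p = 0.0606). The other 18 lists were not called (lowest adjusted p = 0.0556), among them glycolysis (0 higher and 3 lower of 14; 0.854, test upward with a mean of -0.086) and immediate early genes (2 and 0 of 18; 0.804, test upward with a median of -0.16), where Egr2 was higher by 1.23 ± 0.14. The 3 glycolysis genes were 7 without L. major replicate 2 and 1 without L. major replicate 1 or 3 or S. mansoni replicate 1 or 4, and 5 immediate early genes were lower without S. mansoni replicate 2. Keratinocyte genes counted 0 higher and 3 lower of 7 (0.0722), or 0 and 4 adjusted over the list alone; 1 was lower without L. major replicate 1 or S. mansoni replicate 3, 6 without L. major replicate 2 and 0 without S. mansoni replicate 1 or 4. Follicular helper genes counted 0 higher and 5 lower of 10, the same adjusted over the list alone (adjusted p = 0.0966); 3 were lower without L. major replicate 1 or S. mansoni replicate 3 and 2 without L. major replicate 3 or S. mansoni replicate 1. Fibroblast genes counted 0 and 4 of 6, the same adjusted over the list alone (0.0771), with 0 lower without L. major replicate 1 or S. mansoni replicate 1 or 4 and 2 without L. major replicate 3 or S. mansoni replicate 3. Endothelial genes counted 0 and 4 of 6, or 0 and 5 adjusted over the list alone (0.0556), with 0 lower without L. major replicate 3 or S. mansoni replicate 1, 1 without L. major replicate 1 or S. mansoni replicate 4 and 2 without S. mansoni replicate 3. B cell genes counted 1 and 3 of 9, the same adjusted over the list alone (0.386), with 1 lower without L. major replicate 3. Gp9 of the platelet list, too small to test and named after its values were seen, was lower by -0.20 (adjusted p = 0.0377).

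Il2 was lower by -0.25 ± 0.081 (adjusted p = 0.0416), a call lost without L. major replicate 2 (0.0963) or 3 (0.0954) or S. mansoni replicate 1 (0.111) or 4 (0.0842). Prdm1 (0.59 ± 0.29, adjusted p = 0.129), Irf4 (-0.35 ± 0.13, 0.0587), Ifng (0.58 ± 0.33, 0.181), Ctla4 (-0.20 ± 0.081, 0.0840), Bach2 (-0.35 ± 0.17, 0.130), Foxo1 (-0.16 ± 0.081, 0.147), Foxo3 (-0.0035 ± 0.071, 0.972), Cd2ap (-0.46 ± 0.17, 0.0565), Mir182 (-0.085 ± 0.082, 0.418) and Mir10a (-1.25 ± 0.62, 0.133) were not called. Between the infections limma called 4499 genes, 1773 higher in S. mansoni and 2726 lower, with a median absolute log2 change of 0.34, and 195 changed at least 2-fold, 158 up and 37 down. The share higher was 39.4%, against 50.1% under a second quantile normalization (1131 and 1127) and 66.8% with each array centred on its median (1969 and 977). The count was 1655 without L. major replicate 3, 1711 without S. mansoni replicate 1, 1669 without S. mansoni replicate 4, 218 with only the 2 groups in the fit and 130 with the SD of each array as a covariate, added after seeing the data. With only the 2 groups in the fit, 22 of the 50 named calls were lost, Hspa1a (0.109), Gata3 (0.0918), Ccr7 (0.0594) and Il23r (0.109) among them, with the same fold changes. The SD covariate ended 35 of the 50, and left those of Plac8, Fgl2, Nkg7, Tbx21, Pparg, Itga4, Cenpe, Vps37b, Lag3, Egr2, Gzma, Tmem273, Prelid2, Cenph and Gramd3. It also ended the list calls of type I interferon stimulated (adjusted p = 0.843), oxidative phosphorylation (0.167), T cell receptor signalling (0.0759), chemokine receptor and adhesion (0.423) and TGF-beta pathway genes (0.151).

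Against naive, 350 genes were called in both infections: 195 higher in both, 121 lower in both and 34 in opposite directions. Independent lists of those sizes would share 59.7, 26.8 and 83.8. Il10, Gzmb, Ccr2, Ccr8, Prdm1 and Itgae rose in both and Cxcr5 fell in both. Bcl6 and Ccr7 were among 10 genes higher in L. major and lower in S. mansoni, and Cxcr3 and Egr2 among 24 with the reverse. The comparisons share the naive arrays. Across genes, which are not independent replicates, the log2 fold changes had a covariance of 0.0182 (jackknife SE 0.0117), Pearson's r of 0.291 and Spearman's rho of 0.158. In 100 simulated pairs of unchanged groups the covariance was 0.0045 on average and 0.0156 at most, and r was 0.314 on average. The difference of the observed and the mean simulated covariance was 0.0138, near the jackknife SE, and 0 of the 100 pairs reached the observed value. With the naive arrays split between the infections, the covariance had a median of 0.0164 (0.0080 to 0.0216) over 70 splits, and medians of 77, 29 and 7 genes were higher in both, lower in both and opposite.

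**Figure D3:**
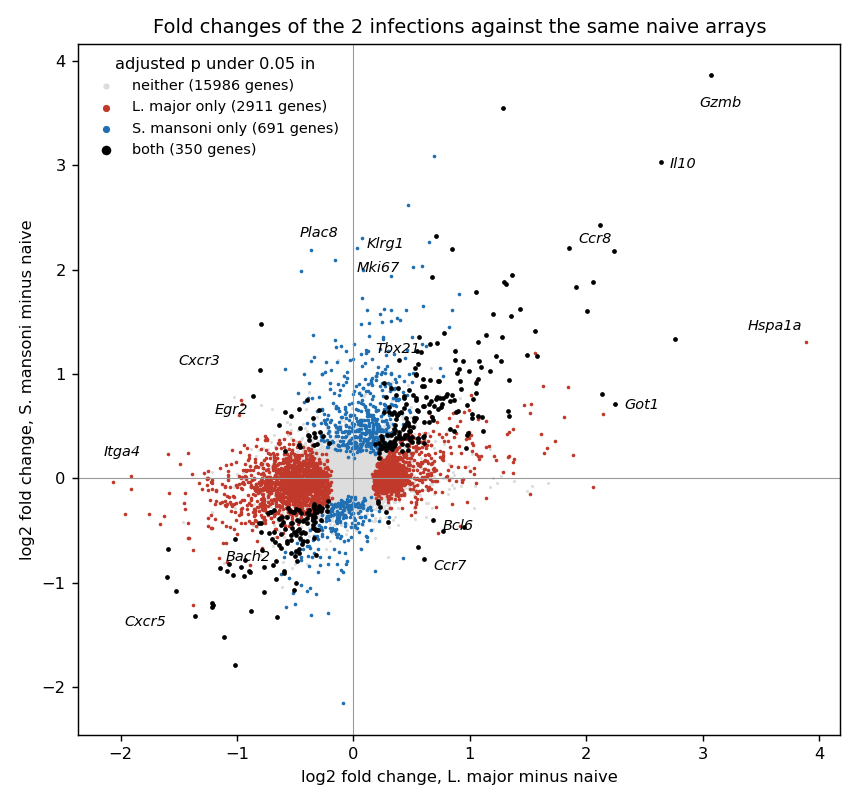
Log2 fold change of each gene in S. mansoni (y axis, n = 4) against that in L. major (x axis, n = 3), both over the same 7 naive arrays. Colours mark 15986 genes called in neither comparison, 2911 called for L. major only, 691 for S. mansoni only and 350 in both.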

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

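The tests of the 3 patterns weighed below, the array SD covariate among them, and the genes named in the last of these patterns and Hspb1, Hspe1 and Hspa8 were chosen after the results were seen; the counts over other splits of the arrays were planned.

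Single arrays stood apart from the rest of their group in 13 of 226 groups of array values for the named genes (5.75%) and 2 of 68 groups of list means (2.94%), and chance gives about 1 in 20. On naive replicate 4, Cd3d was at 11.57 (other naive arrays 11.77 to 11.85), Dgat1 at 8.65 (8.97 to 9.17), Gbp3 at 8.40 (8.71 to 8.91) and Got1 at 8.63 (9.08 to 9.38). On naive replicate 7, Bcl6 was at 8.70 (8.18 to 8.39), Gzma at 6.22 (6.39 to 6.51) and Pparg at 7.66 (7.33 to 7.47). Fgl2 was at 8.27 on naive replicate 1 (7.85 to 7.96), Kif11 at 6.19 on naive replicate 5 (6.64 to 6.87) and Ctsw at 8.04 on naive replicate 6 (7.85 to 7.92). Among the S. mansoni arrays, Cox5a was at 10.32 on replicate 1 (9.82 to 9.89), Hk2 at 7.51 on replicate 3 (7.32 to 7.33) and Actn1 at 8.09 on replicate 4 (7.78 to 7.81). The oxidative phosphorylation list mean, minus naive, was 0.033 on S. mansoni replicate 2 (others 0.22 to 0.25), and the endothelial list mean was -0.049 on naive replicate 5 (-0.0025 to 0.026). The L. major group, with 3 arrays, was too small for this rule.

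Among the named genes, 6 were called in opposite directions in the 2 infections, and the difference between the infections was tested directly for each. They were picked for opposite calls against the same naive arrays. A difference in the direct test was therefore all but fixed in advance and adds no separate support. The calls of Ccr7 and Cxcr3 in L. major and of Bcl6 in S. mansoni were lost without several single arrays and with the SD covariate. Bcl6 differed by -1.08 (adjusted p = 1.9e-04; 0.68 in L. major and -0.40 in S. mansoni), Ccr7 by -1.39 (0.0012; 0.61 and -0.78) and Gramd3 by -1.42 (8.9e-06; 0.95 and -0.47). Cxcr3 differed by 1.84 (0.0010; -0.80 and 1.03), Egr2 by 1.23 (1.7e-04; -0.59 and 0.64) and Prelid2 by 2.26 (1.7e-04; -0.79 and 1.47).

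Other splits of the arrays into groups of the same sizes tested whether chance could be excluded. For L. major against naive, 1 of 100 splits, the real one, gave as many as 3261 genes (highest other 108), and for S. mansoni against naive 1 of 100 gave as many as 1041 (highest other 0). Between the infections 1 of 35 gave as many as 4499 genes, with 3340 as the highest other, from the split that set S. mansoni replicate 2 with the L. major arrays. The 2 counts against naive stood far above those of any other split run, which argues against chance for them. Between the infections 1 of 35 is under the share of 0.05 fixed in advance. It is also the lowest share possible and another split came to 3340, so chance is not taken as excluded for that count. For the gene lists chance cannot be excluded either: 13 of 100 splits gave as many as the 10 called for L. major (highest other 13), 7 of 100 as many as the 20 for S. mansoni (21) and 2 of 35 as many as the 16 between the infections (17).

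Most of the changes called for L. major were under 2-fold (3073 of 3261). Of those among the genes below the median signal 87.3% were higher (1006 of 1153), and above the median signal 68.1% were lower (1308 of 1920), the pattern that a narrower range of signal on the L. major arrays would give. Without L. major replicate 3, which had the lowest SD, 961 of the 3073 were still called, so this array may account for a large part of them. For the 188 changes of at least 2-fold neither test decides: with the array SD as a covariate 76.8% of the median change was left (1.21 before, 0.93 after, with a median SE of 0.24 and 0.28), and 143 were still called without the array. The infection itself stays open as a cause of both kinds of change, since the covariate is confounded with the groups. The labels give no tissue, so infection cannot be told apart from a difference of tissue between the groups.

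For the heat shock genes, higher in L. major, keratinocytes in the sort are argued against as the whole cause: the keratinocyte list mean was 0.014 on L. major replicate 2, within the naive range, and 0.14 on replicate 3, just above the highest naive array (0.12), against 1.84 on replicate 1. The heat shock list means of replicates 2 and 3 were 1.20 and 0.86, the lower of them 0.54 above the highest naive array. Stress before or during sorting that varies between arrays may contribute, as 8 of the 8 measured heat shock genes varied within the naive or the S. mansoni arrays by at least 0.5 of their L. major difference. Of these, Hspa1a (3.89, with a range of 0.41 in naive and 3.64 in S. mansoni) and Hspb1 (0.64, with 0.19 and 0.46) did so only within the infected S. mansoni arrays, and Hspe1 and Hspa8 differed by only 0.12 and 0.29. Within the naive arrays the list mean fell into 2 sets, -0.33 to -0.12 on replicates 1 to 4 and 0.23 to 0.32 on replicates 5 to 7. An effect of infection stays open and was not tested.

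The labels describe female animals, yet on 13 of the 14 arrays the Y-linked genes Kdm5d, Eif2s3y and Uty were above the array's median gene. On those arrays Xist, expressed from the inactive X chromosome of females, was below the median gene. These values argue against the female label for the 13 arrays, and male animals under a female label could give them. L. major replicate 1 was the exception in Xist alone, at 11.15 against 6.63 to 7.12 on the others. Its Y-linked genes also lay above its median gene of 7.75, so this array held markers of both sexes. The Y-linked genes were lowest on L. major replicates 1 and 3, with Kdm5d at 8.51 and 8.53, Eif2s3y at 9.06 and 8.94 and Uty at 8.14 and 7.96. All 7 measured keratinocyte genes were highest on L. major replicate 1, with Krt5 at 10.23, Krt14 at 9.84 and Krt10 at 11.03. Skin RNA of a female mouse is therefore a candidate source of its Xist, although a sort by CD4 and Foxp3 would remove keratinocytes. Ifi202b was also far higher on that array, at 8.70 against 4.06 to 4.65 on the other 13. No biological explanation was tested, since the labels give all animals 1 sex.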

How the results depend on the processing

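The alternatives with weights per group and with the array SD as a covariate were chosen after seeing the data; the others were planned. For L. major against naive, the 3261 genes became 1005 with array weights, 786 with weights per group, 247 with the SD covariate, 188 with a 2-fold threshold, and 1317 to 5121 when each array was left out. For S. mansoni against naive, the 1041 became 1575 with array weights, 1891 with only the 2 groups, 146 with a 2-fold threshold, and 692 to 916 on leaving out each array. Between the infections, the 4499 became 700 with array weights, 636 with weights per group, 2258 with a second quantile normalization, 2946 with median centring, 2248 among the genes above the median signal, 218 with only the 2 groups, 130 with the SD covariate, 195 with a 2-fold threshold, and 1655 to 5974 on leaving out each array. Keeping the genes above the median signal leaves fewer genes to test. Leaving out an array leaves fewer samples, which does not account for counts that rose, such as 5121 without L. major replicate 2. The cause was not tested for these or for the other settings. With the replicate number as a block, the counts were 199, 442 and 673. The arrays of a number did not all correlate best with each other. With so few arrays per group this cannot decide whether the numbers pair them, and the labels do not say what a number stands for. With an estimated correlation, the lists called were 0 of 10, 12 of 20 and 0 of 16. The covariance of the infections' fold changes was 0.033 among the genes above the median signal and 0.0117 to 0.0246 on leaving out each array.

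Of the named calls, 22 of 49 for L. major, 48 of 58 for S. mansoni and 15 of 50 between the infections passed the adjusted p threshold in every setting in which they were tested, and no called gene changed direction. The 2-fold threshold is not counted here, and genes below the median signal were not tested in the setting that left them out. The SD covariate ended 24, 3 and 35 of them, and leaving out single arrays ended 4, 5 and 7. The direction of genes that were not called turned in places, and the cause was not tested. For L. major, with the SD covariate Tbx21 was -0.042, Ifng -0.15 and Foxo3 0.024; Foxo3 was 0.037 with quantile normalization and 0.029 with the block, Il4 0.0094 with array weights and Mir182 -0.046 with quantile normalization. On leaving out each array, Tbx21 ran from -0.030 to 0.30, Foxo3 from -0.060 to 0.037, Il4 from -0.096 to 0.071, Mir182 from -0.017 to 0.14 and Mir10a from -0.0044 to 1.91. For S. mansoni, Foxo3 was 0.018 with median centring; Mir182 was 0.025 with quantile normalization, 0.018 with median centring, 0.035 with the block and 0.0030 with the SD covariate, which put Mir10a at -0.29. On leaving out each array they ran from -0.037 to 0.020, -0.034 to 0.032 and -0.0038 to 0.054. The type I interferon list turned downward with the SD covariate (adjusted p = 0.990). Between the infections, Foxp3 was 0.094 with the SD covariate, Foxo3 0.060 with median centring and Mir182 0.071 with quantile normalization, and they ran from -0.28 to 0.052, -0.044 to 0.053 and -0.15 to 0.010 on leaving out each array, with Mir10a from -1.89 to 0.024. A test for miR-182 and miR-10a seed sites in the 3' untranslated regions of changed genes was not run.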

Other observations

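The observations below, and the genes named in them, were chosen after their values were seen. Ifi202b was at 8.70 on L. major replicate 1 and at 4.06 to 4.65 on the other 13 arrays. Hsph1 was at 9.24 to 9.62 on naive replicates 1 to 4 and at 10.89 to 11.23 on naive replicates 5 to 7. The heat shock list mean split the same arrays, at -0.33 to -0.12 against 0.23 to 0.32. These differences were not tested. Hspa1a was at 8.28, 11.92, 9.78 and 9.58 on S. mansoni replicates 1 to 4, Fosb at 8.76, 11.22, 10.81 and 8.83, and Ifng at 8.17, 9.43, 9.31 and 7.85. On the naive arrays Hspa1a was at 8.42 to 8.83 and Fosb at 8.33 to 8.90.

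Of 347 measured genes whose symbol begins with Zfp, 11 rose and 73 fell for L. major against naive (21.0%, against 7.56% of the other genes), and 2 rose and 8 fell for S. mansoni. For L. major 34 fell without L. major replicate 3 (9.80% against 3.68%), 33 with array weights (9.51% against 2.99%), 71 with a second quantile normalization, 74 with median centring and 4 with the array SD as a covariate (1.15% against 0.47%). For S. mansoni, where 2.31% fell against 1.71% of the other genes, 6 fell with a second quantile normalization (1.73% against 2.16%), 3 with median centring (0.86% against 1.24%), 17 with array weights (4.90% against 2.97%) and 21 with the SD covariate (6.05% against 2.78%). The difference between the infections in these shares was not tested. Other genes called in opposite directions in the infections were Cst7 (-0.86 in L. major and 0.79 in S. mansoni), Itih5 (-0.40 and 0.75), Cd83 (0.55 and -0.66) and Emb (0.77 and -0.50).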
